A study of Mus musculus and Homo sapiens with 33 samples.

How the data were processed

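The series covers 33 total RNA libraries, 3 in each of 11 groups. LLC1, a mouse Lewis lung carcinoma line, was sampled after 48 h with DMSO or with 1 of 6 drug treatments, and again after overexpression of the circular RNA cEmsy or transfer of an empty vector. H358, a human non-small-cell lung cancer line, was sampled after overexpression of cEMSY or with an empty vector. The labels number the libraries of a group from 1 to 3 and do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, ribosomal RNA was depleted and stranded libraries were made. The submitters' processing notes name FastQC, STAR, featureCounts and MultiQC and the builds mm10 and hg19, without versions or roles. The circular RNA caller, the tests behind the authors' selections and the quantifier of each table are not given in the sources used here.

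The drug panel came as a table of signal values deposited by the authors for 472 circular RNAs in 21 libraries, each named by the positions of its back-splice junction. The unit is not named; the values may be shares of the circular RNA signal of a library, in which case higher means a higher share. The authors had chosen the rows as differentially expressed, per the labels, so the number of circular RNAs that did not change is unknown. On the mm10 annotation (GENCODE M21), 430 of the 472 rows (91.1%) had a start on an annotated exon start and an end on an annotated exon end. In 421 rows both ends lay in 1 transcript, 41 lay inside a gene without that, and 10 were spanned by no annotated gene. Host genes are named from position, and a row is a circular RNA, not its host transcript. No row overlapped Emsy, so cEmsy itself was not analysed here in the drug panel.

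Within a library, value times length fell on whole multiples of 1 constant, where length is the spliced length between the junction ends or the genomic span. With a tolerance of 0.002 reads, 439 of the 472 rows (93.0%) gave whole reads in every library where they were above 0. The share of whole values per library ranged from 89.5% to 100.0%. These reads served only to describe depth in back-splice reads, not total sequencing depth. They summed to between 307 and 8921 per library, and no value resolved to whole reads stood for fewer than 2. On a length of 1000 nt, 1 read was worth between 144 and 337 units in DMSO libraries, from 4 or 5 rows above 0 in each. In dactinomycin libraries it was worth between 22.1 and 27.1. A value of 0 in DMSO is therefore a weaker statement than a value of 0 after dactinomycin. The reads cover counting error only, since molecules were not tagged.

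The LLC1 overexpression table was deposited by the authors as a signal per gene in 6 libraries, also restricted to rows they had called changed. It holds 2509 rows, of which 1786 carry mouse gene identifiers and 723 are unannotated loci that the authors numbered. The unit is not named, the smallest values fall on long genes, and no read steps were found, so the depth is unknown. The control columns carry a group name without a link to single labelled libraries. Emsy and Tardbp were not analysed here in LLC1.

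For H358 the authors' deposited comparison was used: a mean signal over all libraries, a log2 fold change, its standard error and statistic (score columns), and a p-value with its adjusted value, per the file headers. The column names are those of a DESeq2 result table, per the file headers. It holds 20347 genes, and in all 20347 the statistic equals the fold change over its standard error within 0.001. An adjusted p-value was absent for 1193 genes, which were left without a call. Values per library and depth were not used here, so no own test, left-out library or paired fit exists for H358.

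Values were analysed with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), and p-values were adjusted by Benjamini-Hochberg to 0.05. Fold changes on that scale understate changes of low genes. The drug panel was fitted once over all 21 libraries without a filter, and adjusted within each treatment. LLC1 genes needed a mean of 0.5 or more, which kept 2111 rows. The design had foreseen count tests as well as limma; the files held no counts, so limma was used. In H358 the authors' adjusted p-value was taken, and gene lists were tested with camera in limma on the authors' statistic, with a preset correlation of 0.01 over 23 lists. For LLC1, where rows were selected, Fisher's exact test compared rising with falling members of a list against the other called rows, for lists with 5 or more called members. The lines were matched by upper-cased symbol. Their difference was tested as the difference of fold changes over the root of the summed squared errors with 8 degrees of freedom. Fisher's exact test of direction among genes called in both lines was chosen after seeing the data, because a planned test over all tested genes is void for rows the authors selected. The tables were scaled separately, so the size of a difference between them is not interpreted.

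The fits were tested on simulated data with 200 changed rows. In the drug panel (472 rows) simulated changes of 4 log2 units were recovered in 32% to 43% of cases. Changes of 2 units were recovered in 18% to 30%, with at most 4.8% false calls. The simulated values were normal noise around the mean of each row over all libraries, without a floor at 0. Most real rows are at 0 in every DMSO library, so these shares do not carry over to the real panel. In LLC1 (2111 rows) the shares were 100% and 99%, with 3.4% false calls. Each check was a single draw. Camera on simulated statistics for 20347 genes called the 1 shifted list and 0 of the others.

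Named genes followed a rule set before the data were examined. It took EMSY and TARDBP, the 8 largest increases and 8 largest decreases among called genes with official symbols, up to 4 members of each list, and a fixed set of cell-death and interferon genes. In LLC1 the largest changes also needed complete separation of the groups and a mean of 1 in the higher group; in H358, without values per library, the authors' mean had to reach 20, only protein-coding genes were ranked, and separation could not be required. These departures were made after the tables were seen. The results of 1 gene list and of some genes that the rule names are not reported here. In the drug panel the rule took up to 4 circular RNAs per treatment and direction, and up to 8 that changed in most treatments. Alternatives were a replicate block, left-out libraries, pseudocounts of 0.1 and 5, stricter or no filters, median-centred values, separate fits per treatment and a minimum fold. For H358, adjustment over all p-values and a mean of 50 or more, and the camera alternatives, were chosen after seeing the data. Python 3.11.15 with scipy 1.17.1 ran the other steps.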

Results

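Total RNA was sequenced from 21 LLC1 libraries in a drug panel, 6 LLC1 libraries with cEmsy overexpression or empty vector, and 6 H358 libraries with cEMSY overexpression or empty vector, with 3 libraries per group. The drug panel addressed which circular RNAs change when LLC1 cells meet agents used to provoke immunogenic cell death, a form of cell death that alerts the immune system. Doxorubicin was labelled 4 mM, bortezomib 100 nM, oxaliplatin 500 uM and dactinomycin 1 uM. The combinations were (R)-crizotinib at 10 uM with cisplatin at 50 uM, and pemetrexed at 2.5 uM with cisplatin at 2.5 uM, all for 48 h. The series description names (R)-crizotinib without cisplatin for that arm, whereas the sample labels and the column headers name both, and these were followed. Circular RNAs form when a downstream splice donor joins an upstream acceptor, and the table lists 472 of them.

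Dactinomycin, a transcription inhibitor, and oxaliplatin, a platinum compound that crosslinks DNA, gave the broadest sets of listed circular RNAs. Dactinomycin libraries held 435 ± 5.0 (SD, n = 3) of the 472 above 0 and oxaliplatin libraries 353 ± 15.7 (SD, n = 3). Crizotinib plus cisplatin gave 174 ± 52.3 (SD, n = 3), with 146, 141 and 234 in single libraries. Pemetrexed plus cisplatin gave 50.3 ± 4.7, bortezomib, a proteasome inhibitor, 46.7 ± 7.6, and doxorubicin 44.7 ± 11.5 (SD, n = 3 each). DMSO libraries held 4.7 ± 0.6 (SD, n = 3), and 467 of the 472 circular RNAs were listed at 0 in all 3. The rows were those the authors had called changed, and DMSO libraries had fewer back-splice reads (307 to 350 in these rows) than dactinomycin libraries (7996 to 8921). Treatments with more circular RNAs above 0 also tended to have more back-splice reads, 4012 to 4838 after oxaliplatin, 2285 to 4146 after crizotinib plus cisplatin and 553 to 1590 after the other 3 treatments. The third crizotinib plus cisplatin library had 4146 and the others 2285 and 2529. The reads counted are those of the listed circular RNAs, so they are not an independent measure of depth.

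**Figure D1:**
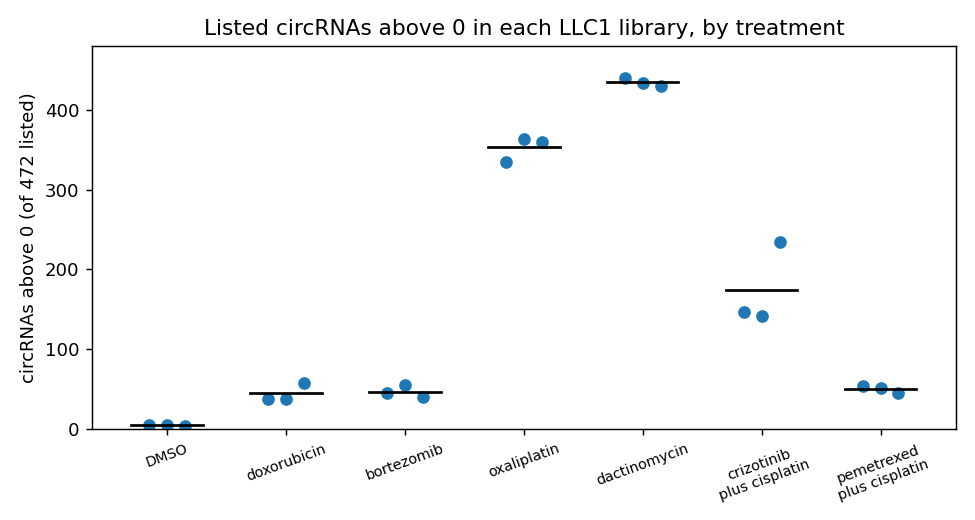
Number of the 472 listed circular RNAs above 0 (y axis) in each library (points) of the DMSO group and the 6 treatments (x axis), with the group mean as a bar. Dactinomycin libraries hold 430 to 440, oxaliplatin libraries 335 to 364 and DMSO libraries 4 or 5.

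With limma, 438 circular RNAs passed an adjusted p of 0.05 for dactinomycin (436 higher and 2 lower than DMSO), 331 for oxaliplatin (329 higher, 2 lower) and 110 for crizotinib plus cisplatin (108 higher, 2 lower). Pemetrexed plus cisplatin gave 7, bortezomib 5 and doxorubicin 3, all higher. With single libraries left out these ranged from 4 to 15, 5 to 12 and 3 to 7. Fitted with DMSO alone, bortezomib and doxorubicin gave 9 each. Centring each library on its median changed the split to 13 higher and 65 lower for dactinomycin and to 18 higher and 125 lower for oxaliplatin, since the median row is 0 in DMSO. Without the third crizotinib plus cisplatin library, with 234 above 0, 81 circular RNAs passed. Because p-values were adjusted within each treatment, a treatment with few calls needed a smaller p-value to pass. Counts of calls, and the number of treatments in which a circular RNA passed, are therefore not directly comparable between treatments.

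A circular RNA of 9 exons in Ttc3, a ubiquitin ligase gene (chromosome 16, 94383912 to 94393174, plus strand, mm10), passed in all 6 treatments and was listed at 0 in all DMSO libraries. Its value was 5212 ± 3454 after bortezomib, 4883 ± 1409 after doxorubicin, 3666 ± 1000 after pemetrexed plus cisplatin and 2145 ± 1913 after dactinomycin (SD, n = 3 each). A circular RNA of 2 exons in Spen (chromosome 4, 141516836 to 141522392, minus strand) also passed in all 6, at 2996 ± 1371 after crizotinib plus cisplatin and 659 ± 587 after dactinomycin (SD, n = 3 each). Circular RNAs of Cep350 (chromosome 1, 155953154 to 155962560) and of Tbc1d14 (chromosome 5, 36571296 to 36572037) passed in 5 treatments. Those of Neil3, which encodes a DNA glycosylase (chromosome 8, 53599099 to 53609538), and of Gstcd (chromosome 3, 133062566 to 133085025) passed in 4. After pemetrexed plus cisplatin the calls for Cep350 and Gstcd were lost without any 1 of the DMSO libraries (adjusted p up to 0.0722 and 0.0858), and that for Tbc1d14 was lost in at least 1 fit without a single library (up to 0.0722), and that for Gstcd also without the third treated library (0.0565). In Neil3 the value was 3240 ± 97.2 after doxorubicin (SD, n = 3) and listed at 0 after bortezomib. Circular RNAs of Psd3 (chromosome 8, 67904117 to 67908889) and Rasa2 (chromosome 9, 96576286 to 96611499) passed in 3, at 1766 ± 276 and 758 ± 132 after dactinomycin (SD, n = 3 each).

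A circular RNA of 3 exons in Rnf114 (chromosome 2, 167507047 to 167511326) reached 8101 ± 4910 after bortezomib (SD, n = 3; adjusted p = 0.00107) and was listed at 0 in all libraries of 5 groups, including DMSO. After dactinomycin, circular RNAs of the spindle checkpoint gene Bub1b (chromosome 2, 118631759 to 118635277), Erbin (chromosome 13, 103884143 to 103889285), Dennd1b (chromosome 1, 139053346 to 139062971) and the deadenylase subunit gene Cnot2 (chromosome 10, 116517317 to 116549175) stood at 5352 ± 586, 4979 ± 557, 4544 ± 891 and 4189 ± 991 (SD, n = 3 each). In oxaliplatin libraries the same circular RNAs of Bub1b, Erbin and Dennd1b stood at 4418 ± 673, 4408 ± 407 and 4508 ± 857, and one of Ptbp3 (chromosome 4, 59514274 to 59524476) at 4363 ± 726 (SD, n = 3 each). After crizotinib plus cisplatin the largest differences from DMSO that passed were in Spred2 (chromosome 11, 19998120 to 20008477) at 10269 ± 5312, Tlk1 (chromosome 2, 70770004 to 70786995) at 8051 ± 1528 and Rapgef6 (chromosome 11, 54543579 to 54568496) at 6136 ± 3838 (SD, n = 3 each), with Ptbp3 next at 5113 ± 1682 (SD, n = 3). Each of these was listed at 0 in DMSO, so no fold is given. On median-centred values the calls for Bub1b, Erbin and Dennd1b after both drugs, for Cnot2 after dactinomycin and for Ptbp3 after oxaliplatin were lost (adjusted p from 0.266 to 0.692). The Dennd1b circular RNA stood at 10637 ± 2773 after doxorubicin (SD, n = 3) without passing (limma, adjusted p = 0.0631).

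A circular RNA of 16 exons in Ect2, a regulator of cytokinesis (chromosome 3, 27115396 to 27145059, minus strand), was lower than in DMSO after 3 treatments. DMSO libraries stood at 5741 ± 3579, oxaliplatin libraries at 173 ± 152 and crizotinib plus cisplatin libraries at 331 ± 574 (SD, n = 3 each), and dactinomycin libraries were listed at 0. The adjusted p-values were 0.000211 for dactinomycin, 0.0151 for oxaliplatin and 0.0103 for crizotinib plus cisplatin, and the last 2 were lost without the third library of that treatment (0.092 and 0.0552). A junction in Nfat5 (chromosome 8, 107334912 to 107335484), with ends not both on annotated exons of 1 transcript, stood at 9639 ± 6937 in DMSO, 45.3 ± 78.5 after oxaliplatin and 64.2 ± 111 after dactinomycin (SD, n = 3 each). A junction that no annotated gene spans (chromosome 15, 61864604 to 62038201) stood at 266 ± 113 in DMSO (SD, n = 3). It was listed at 0 after crizotinib plus cisplatin. It stood at 22.8 ± 4.26 after oxaliplatin and 25.6 ± 5.74 after dactinomycin (SD, n = 3 each) without passing (limma, adjusted p = 0.101 and 0.0988). In the other treatments its means lay between 57.4 and 168. Its 173598 nt may hold genes. Junctions with the same start and ends at 61866498, 61878292 and 61897456 passed as higher in 2, 3 and 3 treatments.

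Of the 472 circular RNAs, 333 passed in the same direction in 2 or more treatments, 331 higher and 2 lower; on median-centred values 68 did, 17 higher and 51 lower. All treatments share the DMSO libraries, and the p-value needed to pass differed between treatments. In 100 simulated sets of unchanged treatments against these libraries the mean was 0. The simulation did not model the authors' choice of rows as changed, so it gives no chance level for the 333. Dactinomycin and oxaliplatin shared 311 higher circular RNAs where independent lists of those sizes would share 303.9, and oxaliplatin and crizotinib plus cisplatin shared 91 against 75.3. Dactinomycin and crizotinib plus cisplatin shared 98 against 99.8. Most pairs that include a treatment with few calls shared more than independent lists would. Only dactinomycin, after which most rows passed, shared fewer, with bortezomib and with pemetrexed plus cisplatin. Pemetrexed plus cisplatin shared 4 with bortezomib against 0.1 and 6 with crizotinib plus cisplatin against 1.6. Dactinomycin shared 4 with bortezomib against 4.6 and 5 with pemetrexed plus cisplatin against 6.5. With 3 DMSO libraries the controls could not be split to separate a shared response from shared controls. Between treatments, doxorubicin differed from dactinomycin in 384 circular RNAs (4 higher and 380 lower after doxorubicin). Oxaliplatin differed from crizotinib plus cisplatin in 194 (178 higher, 16 lower), and crizotinib plus cisplatin from pemetrexed plus cisplatin in 73 (68 higher, 5 lower). On median-centred values the first split became 82 higher and 13 lower after doxorubicin, and the second 19 higher and 259 lower after oxaliplatin. Doses and the value of 1 read on 1000 nt differ between treatments. That read was worth 82.7 to 172 units after doxorubicin, 22.1 to 27.1 after dactinomycin and 38.3 to 47.1 after oxaliplatin. It was worth 29.6 to 82.4 after crizotinib plus cisplatin and 124 to 142 after pemetrexed plus cisplatin. These contrasts therefore do not separate a drug difference from an unequal value of 1 read. If values are shares of circular RNA signal, a drug may itself change that value.

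In LLC1 cells with cEmsy overexpression, listed genes of mitosis and DNA replication fell and the 5 listed of 32 interferon-stimulated genes rose. The cell cycle list had 25 of its 30 members in the table, and all 25 fell. Top2a, the DNA topoisomerase of dividing cells, went from 76.0 ± 1.65 to 4.66 ± 0.563 (SD, n = 3 per group), and the mitotic motor gene Kif11 and the mitotic kinase genes Aurka and Plk1 fell by 3.55, 3.54 and 3.28 on the log2 scale (SE 0.09, 0.07 and 0.08). Other named genes moved too: the cyclin gene Ccng1 rose by 2.84 ± 0.07 (SE), the death receptor gene Fas by 2.07 ± 0.10, Ei24 by 1.95 ± 0.08 and Perp by 1.77 ± 0.06 on the log2(value + 1) scale.

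Among the 2111 tested rows, 2110 passed an adjusted p of 0.05 in limma, 999 higher and 1111 lower with overexpression, and 2106 had groups that did not overlap, where chance gives 10%. This reflects the authors' choice of rows and says nothing of the share of all genes that changed. Against the other called rows, the lists tilted down for the cell cycle (Fisher's exact test, two-sided, adjusted p = 6.12e-07 over 6 lists) and for immediate early genes (6 of 6 fell, adjusted p = 0.0485). Of the lists given here, that of interferon-stimulated genes tilted up (5 of 5 rose, adjusted p = 0.0474). The test counted each gene as independent. Genes of a list were measured in the same libraries and may move together, so these p-values may overstate the evidence. The other called rows include unannotated loci, which cannot be list members. Of all 723 such loci 452 were lower and 271 higher, which may favour an upward tilt. A comparison with annotated genes alone was not run. All called members also passed when adjusted over the list alone.

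Among the 8 largest increases were the carboxylesterase genes Ces2e, from 0.233 ± 0.0415 to 34.8 ± 3.87, and Ces2f, from 0.176 ± 0.0485 to 10.6 ± 0.791 (SD, n = 3 per group). Dcxr rose by 3.52 ± 0.19 (SE), Glipr1 by 3.29 ± 0.07 and the alpha-globin gene Hba-a1 by 3.65 ± 0.18. Zscan4c, Zscan4b and Zscan4f, members of a cluster known from early mouse embryos, rose by 3.15 ± 0.10, 3.07 ± 0.09 and 3.07 ± 0.16 (SE). These are near-identical copies, and how reads were shared between them is not known. The largest decreases were Efr3b, from 39.8 ± 7.78 to 0.188 ± 0.0568, Dntt, which adds nucleotides in antigen receptor joining, from 32.6 ± 3.26 to 0.141 ± 0.0534, and Cd209c, from 28.3 ± 1.79 to 0.162 ± 0.0756 (SD, n = 3 per group). Ube2c, a ubiquitin-conjugating enzyme gene of mitotic exit, fell by 3.83 and the epithelial transcription factor gene Grhl2 fell by 3.64 on the log2 scale (SE 0.06 and 0.08).

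Of the interferon-stimulated genes, Irf7 went from 1.34 ± 0.167 to 5.06 ± 0.383 (SD, n = 3 per group). Stat2 rose by 0.93 ± 0.09, Ifi35 by 0.88 ± 0.11 and Oas1a by 0.57 ± 0.10 on the log2(value + 1) scale (SE). Immediate early genes fell, Egr1 from 237 ± 13.3 to 19.6 ± 1.69 (SD, n = 3 per group), and Ier2, Fosb and Egr2 fell by 1.79, 1.52 and 1.40 on the log2 scale (SE 0.10, 0.08 and 0.09). Of the integrated stress response list 5 were listed, 1 rose and 4 fell, among them Fgf21, which fell by 3.21, and Slc7a5, Slc3a2 and Shmt2, which fell by 1.20, 1.10 and 1.08 (SE 0.10, 0.07, 0.07 and 0.06). Of the immunogenic cell death list the 2 listed members fell: the ATP receptor gene P2rx7 by 2.37 (SE 0.10) and Hmgb1, whose product is released by dying cells, by 1.34 (SE 0.10). The DNA sensor gene Cgas fell by 1.32 (SE 0.10), while Ikbke rose by 1.19 ± 0.08 (SE). The integrated stress response and the chemokine lists did not pass (Fisher's exact test, two-sided, adjusted p = 0.378 each). Of the chemokine and cytokine list 1 of 5 rose, Il15 by 1.10 ± 0.08 (SE), and 4 fell, among them Ccl20, which fell by 3.03, and Relb, which fell by 0.95 (SE 0.09 and 0.10).

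Single listed members of other lists were Tapbp (1.37 ± 0.07), Hspa8 (1.23 ± 0.06), Pink1 (1.13 ± 0.12), Hmox1 (1.69 ± 0.11), Ankrd37 (1.66 ± 0.08) and Mmp2 (1.31 ± 0.08), all higher on the log2 scale (SE), and Sdf2l1, which fell by 1.00 (SE 0.13). Insig1 rose by 1.07 ± 0.08 (SE) and Fasn fell by 0.90 (SE 0.08). Lgals9 rose by 1.99 ± 0.12 and Cd80 by 0.93 ± 0.11 (SE), and Ulbp1, which encodes a natural killer cell ligand, fell by 1.16 (SE 0.08). Gsdme fell by 0.82 (SE 0.09). The epithelial genes Krt7 and Napsa rose by 1.56 ± 0.08 and 0.77 ± 0.15 (SE). No member of the mitochondrially encoded, oxidative phosphorylation or proteasome lists was listed. Of the markers of other cell types (13 leukocyte, 8 endothelial, 8 fibroblast and 6 red blood cell) 4 were listed: Cd68 (1.28 ± 0.13), Lyz2 (0.64 ± 0.08) and Hba-a1 were higher and Cd74 fell by 1.11 (SE 0.07).

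**Figure D2:**
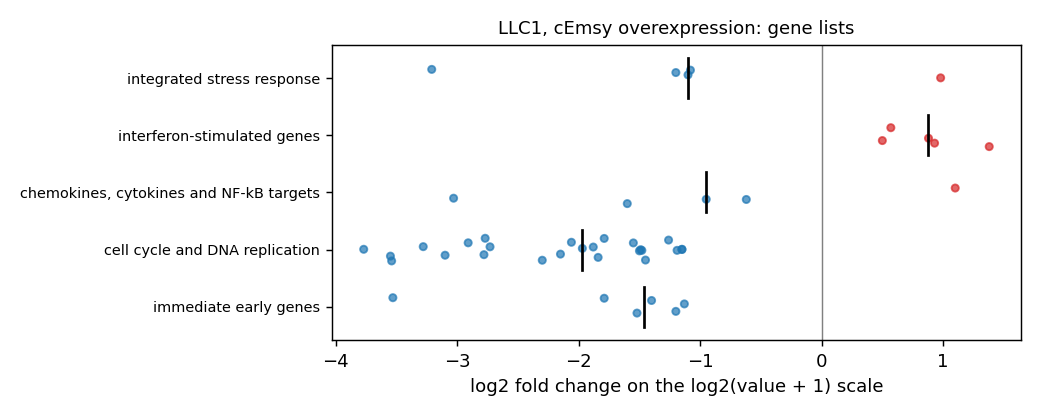
Log2 fold change of cEmsy overexpression over empty vector in LLC1 on the log2(value + 1) scale (x axis) for each listed gene (points, red above 0 and blue below) of 5 of the 6 tested lists (y axis), with the list median as a bar. All 25 cell cycle genes lie below 0 and all 5 interferon-stimulated genes above it.

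In H358 cells with cEMSY overexpression, interferon-stimulated genes and sterol and fatty acid synthesis genes were higher and cell cycle genes lower. EMSY itself rose by 3.84 ± 0.07 (log2, SE) in the authors' deposited table; this gene-level value does not separate circular from linear transcripts. TARDBP, which encodes the RNA-binding protein TDP-43, fell by 0.50 (SE 0.06) in the authors' deposited table. Of 33 interferon-stimulated genes 22 rose and 0 fell, among them CCL5 (7.20 ± 0.15), CXCL10 (6.98 ± 0.77), IFIT2 (6.46 ± 0.14) and RSAD2 (6.35 ± 0.50) on the log2 scale of the authors' deposited table. The interferon genes IFNB1 (7.45 ± 1.33), IFNL1 (8.40 ± 1.22), IFNL2 (8.87 ± 1.24) and IFNL3 (8.81 ± 1.23) rose in the authors' deposited table. The last 2 are near-identical copies. Their levels were low, with authors' means over all libraries of 16.4 for IFNB1 and 42.4 to 62.4 for the IFNL genes.

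In all, 6211 of 20347 genes in the authors' deposited table had an adjusted p below 0.05, 2997 higher and 3214 lower with cEMSY. With an absolute log2 fold change of 1 or more the split was 1264 higher and 550 lower. Camera on the authors' statistic placed 13 of 23 lists past an adjusted p of 0.05. Of the lists given here, the test for interferon-stimulated genes gave 1.94e-59, for sterol and fatty acid synthesis 1.56e-25, for the cell cycle 1.04e-26 and for heat shock genes 6.43e-07 (camera, adjusted p). A correlation estimated from the libraries could not be had without values per library; with a set correlation of 0.05 the list for cytosolic nucleic acid sensing was lost (adjusted p = 0.0802), and the other 12 held. Adjusted over the list alone, 23 interferon-stimulated, 28 cell cycle and 21 sterol genes passed.

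Besides IFNL1, IFNL2 and IFNL3, the 8 largest increases that the naming rule took from the authors' deposited table were VGLL1 (12.55 ± 1.18), LY6G6D (11.28 ± 1.19), SERPIND1 (9.64 ± 1.21), FSTL5 (8.73 ± 1.21) and CCL3 (8.44 ± 1.25). UGT1A8, PLXDC2, KRT4, SFRP4, ACKR3, ITGB6, SPARC and CBLN2 had the largest decreases, from -6.45 ± 1.12 to -3.98 ± 0.50, in the authors' deposited table. The group values behind these folds were not used here.

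Of 22 sterol and fatty acid synthesis genes 19 rose and 1 fell in the authors' deposited table, with SCD, a desaturase gene, at 2.46 ± 0.07, STARD4 at 1.99 ± 0.15 and the regulator gene SREBF1 at 1.69 ± 0.09. Endoplasmic reticulum chaperones rose in 15 of 21 and fell in 0 (camera adjusted p = 1.96e-05), with XBP1 at 1.57 ± 0.08 and DNAJB9 at 0.85 ± 0.15 in the authors' deposited table. The integrated stress response list had 13 higher and 5 lower of 22 (camera adjusted p = 0.000208), led by GDF15 (3.16 ± 0.11), CHAC1 (1.99 ± 0.34), TRIB3 (1.46 ± 0.10) and DDIT4 (1.28 ± 0.09) in the authors' deposited table. CDKN1A, a cell cycle inhibitor gene, stood at 1.75 ± 0.08 and BBC3, which promotes apoptosis, at 1.22 ± 0.24 in the authors' deposited table. Of 14 genes of cytosolic nucleic acid sensing 3 rose and 1 fell (camera adjusted p = 0.0276, 0.0802 with the set correlation of 0.05 and 0.704 on ranks; median 0.01). The RNA sensor genes IFIH1 (2.87 ± 0.16) and DDX58 (2.60 ± 0.13) rose in the authors' deposited table.

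Of 30 cell cycle genes 27 fell and 0 rose, with CDC20 at -1.20 ± 0.08, MKI67 at -0.97 ± 0.09 and CCNA2 at -0.95 ± 0.07 in the authors' deposited table. Heat shock genes fell in 12 of 16 and rose in 2, with HSPA8 at -0.82 ± 0.07 and HSPB1 at 0.73 ± 0.08 in the authors' deposited table. NRF2 targets fell in 11 of 15 and rose in 0 (camera adjusted p = 0.00182), with GCLM at -0.82 ± 0.08 and SLC7A11 at -0.74 ± 0.10 in the authors' deposited table. Circular RNA biogenesis and decay factors fell in 14 of 20 and rose in 0 (camera adjusted p = 1.71e-06), with HNRNPL at -0.79 ± 0.06 and QKI, a splicing factor that promotes circle formation, at -0.77 ± 0.13 in the authors' deposited table. Extracellular matrix genes had 10 lower and 6 higher of 26 (camera adjusted p = 7.54e-06, 0.234 on ranks), with SPARC at -4.22 ± 0.32 and CDH2 at -2.59 ± 0.11 in the authors' deposited table. The lung epithelial list had 5 lower and 1 higher of 9 (camera adjusted p = 0.00182, 0.234 on ranks), with KRT19 at -3.91 ± 0.31 and KRT7 at -1.05 ± 0.06 in the authors' deposited table. Mitochondrially encoded transcripts rose in 8 of 13 and fell in 1 (camera adjusted p = 0.0019), with MT-CO1 at 0.65 ± 0.07 in the authors' deposited table.

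The following 10 lists did not pass. Of the immunogenic cell death list 6 rose and 7 fell of 27 (camera adjusted p = 0.882), with IL6 at 2.40 ± 0.22, LRP1 at 1.13 ± 0.10, HMGB1 at -0.33 ± 0.05 and CALR at 0.14 ± 0.07 (adjusted p = 0.12) in the authors' deposited table. ANXA1, ATF4, CGAS, STING1 and CD274 did not pass in the authors' deposited table (adjusted p from 0.246 to 0.996). HSPA5 stood at 0.26 ± 0.05, B2M at 0.37 ± 0.06 and DDIT3 at 0.90 ± 0.26 in the authors' deposited table. Antigen presentation had 3 higher and 3 lower of 16 (camera adjusted p = 0.915), chemokines and cytokines 8 and 12 of 29 (0.975), and cell death genes 5 and 10 of 25 (0.651) in the authors' deposited table. Oxidative phosphorylation had 6 higher and 3 lower of 23 (0.731), mitochondrial import 4 and 10 of 24 (0.132), and hypoxia 6 and 4 of 20 (0.915) in the authors' deposited table. Checkpoint and natural killer ligands had 4 higher and 3 lower of 17 (0.915), proteasome subunits 1 and 8 of 24 (0.0538, and 0.00437 on ranks), and immediate early genes 9 and 5 of 17 (0.651) in the authors' deposited table. The test direction and the mean or median fold differed in sign for the immunogenic cell death, antigen presentation, chemokine, cell death and checkpoint lists. Single members still moved in the authors' deposited table: CX3CL1 at 4.02 ± 0.54, EGLN3 at 2.69 ± 0.16, PFKFB3 at -1.33 ± 0.05, ULBP1 at 1.68 ± 0.26, PVR at -0.95 ± 0.06, EGR1 at 2.87 ± 0.32 and FOSL1 at -2.26 ± 0.11. Of 7 leukocyte markers 3 were higher, S100A8 (4.85 ± 1.54), S100A9 (3.36 ± 0.61) and CD74 (3.16 ± 0.89), in the authors' deposited table. Another 1 was lower, CD68 (-0.75 ± 0.13), likewise. The authors' means of S100A8 (5.5) and CD74 (11.9) lay under the 20 required for the largest changes, and that of S100A9 was 25.0. Of 5 endothelial markers 1 rose and 1 fell, and 0 of 5 fibroblast and 0 of 3 packaging-cell markers changed in the authors' deposited table.

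**Figure D3:**
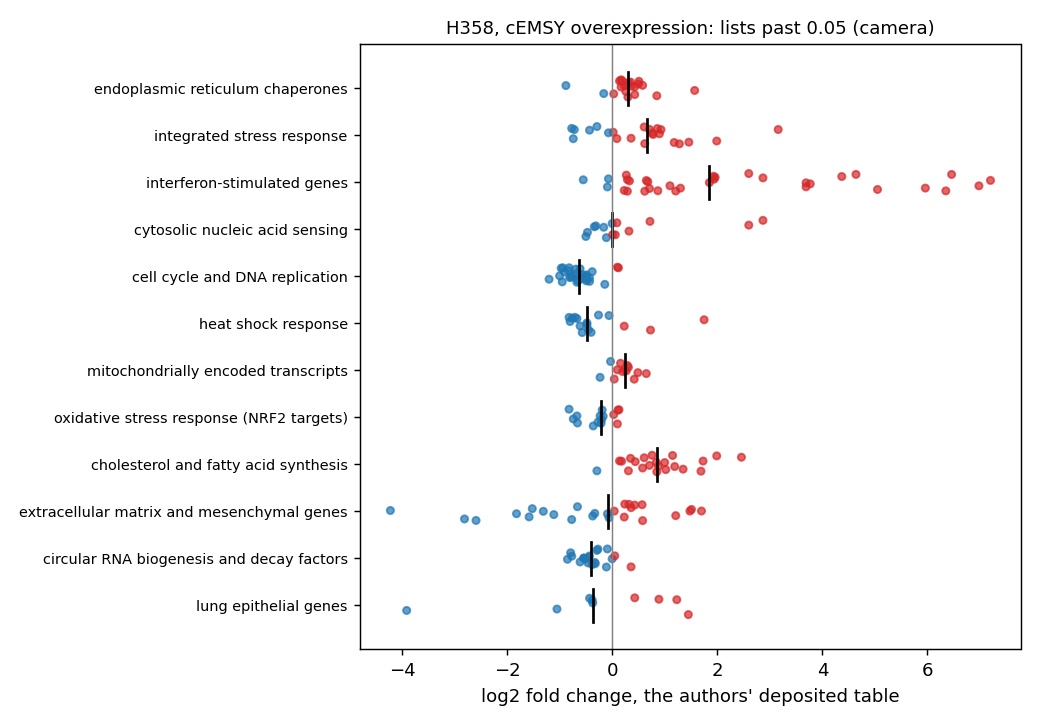
Log2 fold change of cEMSY overexpression over control in H358 from the authors' deposited table (x axis) for each gene (points, red above 0 and blue below) of 12 of the 13 lists past an adjusted p of 0.05 in camera (y axis), with the list median as a bar. Interferon-stimulated genes reach 7.20 and have a median of 1.85, and cell cycle genes have a median of -0.63.

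Between the lines 1124 genes matched by symbol, and 621 passed in both. Of these 512 (82.4%) moved in the same direction, 332 lower and 180 higher, where independent directions would give 53% (Fisher's exact test of direction, two-sided, p = 5.2e-57, with genes not independent). Across the matched genes Spearman's rho was 0.47 and Pearson's r 0.34; genes are not independent replicates and the LLC1 rows were selected. Top2a (-3.77 ± 0.08 in LLC1, -0.82 ± 0.05 in the authors' deposited table for H358) fell in both. Il15 (1.10 ± 0.08 and 1.13 ± 0.11, likewise) and Stat2 (0.93 ± 0.09 and 0.71 ± 0.16, likewise) rose in both.

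**Figure D4:**
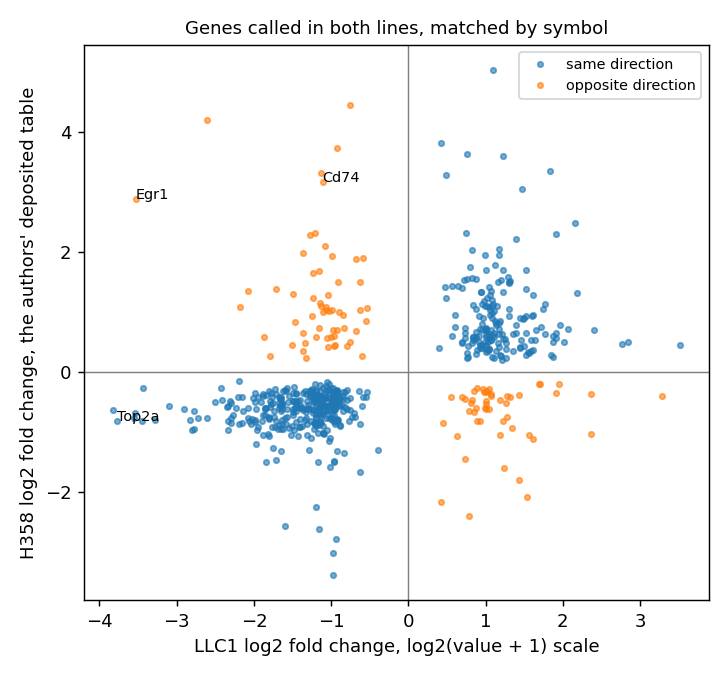
Log2 fold change in LLC1 on the log2(value + 1) scale (x axis) against that in H358 from the authors' deposited table (y axis) for the 621 genes (points) called in both lines. 512 genes lie in the quadrants of the same direction and 109 in the others, Egr1 and Cd74 among them.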

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

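The tests on expected DMSO reads, on near-identical Zscan4 copies, on chromosomes holding both directions and on markers of other cell types were chosen after the result, or a rough estimate of it, was seen. Groups of 3 libraries were not tested for outlying samples. Tests of the difference itself marked the contrasts between treatments: doxorubicin against dactinomycin (384 circular RNAs), oxaliplatin against crizotinib plus cisplatin (194), and crizotinib plus cisplatin against pemetrexed plus cisplatin (73). The value of 1 read on 1000 nt differed between these groups (82.7 to 172 units after doxorubicin and 22.1 to 27.1 after dactinomycin). No test here separates it from a drug difference, and a drug may itself change it. Between the lines, 109 genes passed in both in opposite directions, and all 109 had the difference itself past an adjusted p of 0.05. Folds of opposite sign that both passed nearly always differ, so this test adds little to the signs. Among genes named in either line the LLC1 minus H358 difference in log2 fold change was 2.03 for Cd68, -4.27 for Cd74, -6.40 for Egr1, 2.15 for Ei24, -1.90 for Fasn, 3.69 for Glipr1, 1.90 for Hmox1, 2.05 for Hspa8, -2.05 for Ier2, 1.66 for Ikbke, 2.61 for Krt7, -1.58 for Sdf2l1 and -2.84 for Ulbp1. The 2 tables were scaled separately, so the signs and not the sizes can be read.

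The first pattern is that 467 of 472 circular RNAs were listed at 0 in every DMSO library, where fewer reads could be the cause. The test took the 434 circular RNAs with whole reads that were listed at 0 in every DMSO library. At the highest treated level, 49 of them would have given 20 or more reads over the 3 DMSO libraries. For these 49, that argues against too few reads alone if the level is right. It is the highest of 6 treatments in rows the authors chose as changed, so the level may be too high. The count was 45 when that level came from a treatment with all 3 libraries above 0, and 20 at the dactinomycin level. For the other 385 the median expectation was 6.1 reads, and since the authors chose the rows from an unknown number of candidates, low depth and a true absence cannot be told apart there. An effect of the treatments, or greater stability of circles when transcription is blocked, stays open and untested.

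For the counts of calls, 10 splits of 6 libraries cannot give a share under 0.05. In each of the 6 drug comparisons and in LLC1, 1 of the 10 splits (the real one) gave as many calls. The real counts were 3 for doxorubicin, 5 for bortezomib, 331 for oxaliplatin, 438 for dactinomycin, 110 for crizotinib plus cisplatin, 7 for pemetrexed plus cisplatin and 2110 for LLC1, and the highest of the other splits was 0 in each. Rows that the authors chose as changed make few calls likely in any other split, so this contrast adds no evidence.

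The second pattern is the rise of the Zscan4 cluster in LLC1 with cEmsy overexpression. Reads shared between near-identical copies could move signal from one copy to another without a change in their sum. The summed value of the 8 listed copies was 4.24 ± 0.28 with empty vector and 86.1 ± 10.9 with overexpression (SD, n = 3 each), and the lowest overexpression library stood 17.3 times above the highest empty-vector library, which argues against reads moving among the listed copies as the whole cause; copies outside the table were not analysed here. A rise in the cluster as a whole stays open, as an effect of the circular RNA or of a difference between the cell stocks.

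The third pattern is a set of 70 annotated LLC1 genes with a mean under 0.5 in one group and at least 2 and 8 times more in the other, limits set after the pattern was seen, with 49 higher and 21 lower with overexpression. On 12 of the 13 chromosomes with 3 or more such genes both directions occurred, which argues against gain or loss of whole chromosomes as the cause of the set. Large segments stay open: a permutation p of 0.794 for a difference between chromosomes (100000 permutations) does not show that directions were even, so the bound set before it was seen was wrong. Cells or RNA of another type could bring such genes, but 4 of 36 markers (11.1%) were listed, and because the rows were selected an unlisted marker decides nothing. Separate drift of the cell stocks and an effect of the circular RNA stay open and untested.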

How the results depend on the processing

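The camera alternatives, and for H358 adjustment over all p-values and a mean of 50 or more, were chosen after seeing the data. Centring each library on its median gave 143 calls for oxaliplatin, 78 for dactinomycin, 68 shared circular RNAs (17 higher, 51 lower) and 95 for doxorubicin against dactinomycin, because the median row is 0 in DMSO and above 0 after oxaliplatin and dactinomycin. For oxaliplatin against crizotinib plus cisplatin it gave 278, of which 259 were lower after oxaliplatin, where most had been higher. Fitting each treatment with DMSO alone gave 9 calls for doxorubicin and 9 for bortezomib, the spread then coming from 6 libraries. In LLC1 a mean of 2 or more gave 1253 calls (fewer genes tested) and a minimum log2 fold of 1 gave 1294; in H358 that minimum gave 1814. Camera with a correlation of 0.05 gave 0.0802 for nucleic acid sensing, and camera on ranks gave 0.704 for nucleic acid sensing, 0.234 for extracellular matrix, 0.234 for lung epithelial genes and 0.00437 for proteasome subunits; the cause was not tested.

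With single libraries left out, calls ranged from 3 to 7 for doxorubicin (7 without replicate 1, 5 without replicate 2), 5 to 12 for bortezomib (12 without replicate 1, 8 without replicate 3), 4 to 15 for pemetrexed plus cisplatin (15 and 12 without replicates 1 and 2, 4 without any 1 DMSO library), 306 to 350 for oxaliplatin, 409 to 420 for dactinomycin, 81 to 146 for crizotinib plus cisplatin, 298 to 354 for shared circular RNAs and 2084 to 2109 for LLC1. The contrasts between treatments ranged from 350 to 374, 184 to 215 and 56 to 75. The replicate block gave 3, 5, 330, 437, 105 and 7 calls in the order doxorubicin, bortezomib, oxaliplatin, dactinomycin, crizotinib plus cisplatin and pemetrexed plus cisplatin. Deviations of same-numbered libraries correlated from -0.14 to 0.15, which shows no pairing by number. Rows chosen as changed, most of them at 0 in DMSO, cannot exclude such pairing. No paired analysis was possible in LLC1 because the control columns carry no replicate number tied to a label, or in H358 because the result comes from the authors' table.

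Of 978 values for genes, or circular RNAs in the treatment that named them, under alternatives 961 kept direction and call, 17 for circular RNAs lost the call (8 on median-centred values) and 0 reversed. Count tests, estimated correlations and rotation tests were not run, since no table holds counts and H358 has no values per library here; the drug panel had no filter to make stricter, and no circular RNA of Emsy was analysed here. The value of 1 read limits what a value of 0 in the drug panel means: 1 read in DMSO was worth 9.4 times 1 read after dactinomycin.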

Other observations

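These groups were chosen after their values were seen. In LLC1 with cEmsy overexpression, other multicopy families known from early mouse embryos were higher together with the 8 listed Zscan4 copies: 2 of 2 listed Tcstv genes, 3 of 3 listed Tdpoz genes and 5 of 5 listed Usp17l genes passed with a higher value. Tcstv3 went from 0.763 ± 0.443 to 11.6 ± 3.44 and Tdpoz4 from 1.41 ± 0.111 to 8.24 ± 1.04 (SD, n = 3 per group). Of the 723 unannotated loci 452 had a lower and 271 a higher mean with overexpression, without a test. The rows are those the authors selected, so members of these families outside the table are not counted.

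The immediate early gene Egr1 moved apart between the lines, at -3.53 ± 0.08 in LLC1 and 2.87 ± 0.32 in the authors' deposited table.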
